A study of Arabidopsis thaliana with 8 samples.

How the data were processed

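Expression was measured in Arabidopsis thaliana seedlings on one-colour Agilent arrays that carry annotated genes and short open reading frames (sORFs, small possible coding regions outside the annotated loci). The labels name 4 groups of 2 arrays each: seedlings given the AT13 peptide, non-treated seedlings, wild type, and an overexpressor of AT13. The series title equates AT13 with PROPEP3, the precursor gene, and the AT13 peptide with Pep3, the peptide cut from that precursor. The labels' design text calls the 2 samples of a group biological replicates. They give no dose, treatment time or seedling age.

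Polyadenylated RNA was copied into Cy3-labelled cRNA with an Agilent linear amplification kit from an oligo-dT primer, per the labels' protocols. The 8 scanner files hold spot intensity values extracted with Agilent Feature Extraction 9.5.3.1, per the file headers. Their processed signal is the background-subtracted and detrended intensity of a spot, with no normalization between arrays, per the file headers. The files also hold the mean spot intensity, the local background and quality flags. A value table deposited by the authors for the whole series gives 1 intensity per probe and sample on a linear scale. Its normalization is not given in the sources used here. Every value of its 8 columns lay within 1% of a quantile normalization among the 4 arrays of a slide, rebuilt from the scanner files as the mean of the sorted processed signals. Scale and centring of the table were therefore settled from the data, and its column medians were 70.4 on slide 1 and 76.1 on slide 2.

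The value table and the scanner files disagree about which array is which sample. Each of the 8 columns has a rank correlation of 1 with exactly 1 scanner file. For 2 columns that file is attached to the same sample, and for 6 columns it is attached to another sample. Within slide 1 the table's non-treatment columns match the files attached to peptide 1 and non-treatment 1, and its peptide columns match those attached to peptide 2 and non-treatment 2. Within slide 2 the table's wild type 2 and overexpressor 1 columns match each other's attached files. No source used here says which of the 2 labellings is right. Scanner files were therefore kept under the samples they are attached to, and value-table columns under the samples their headings name. No array was moved to another group on the strength of its values in the main fit. The conflict was found only after the design had been fixed.

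Comparisons were fitted on both sources. The main fit, fixed before the data were examined, took log2 of the processed signal minus the 75th percentile of each array, from the attached scanner files. The fit on the log2 values of the value table had been listed beforehand as an alternative. The main fit called 0 features in either comparison, so the genes named in the text come from the value table, and this choice was made after both results had been seen. Group names in the text follow the value table's column headings unless the attached files are named. The quality flags of each value-table column were taken from the scanner file with the same ranks.

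The array has 37052 spots, of which 1417 are controls and were left out. Of the 35635 other probes, 26985 name 1 annotated locus, 6183 an sORF, 1411 a cDNA accession, 291 several loci and 765 none. Probes are 60 bases long. Symbols came from a RefSeq gene table of assembly TAIR10.1, which held the locus of 26412 gene probes, 10305 of them with a symbol other than the locus. Array coordinates belong to an older build, so coordinates are printed as the array design gives them, and gene lengths come from the gene table. The 39 spots with an outlier flag were left out, and 0 probes were saturated. Between 62.1% and 66.5% of probes were well above background on an array. A feature was tested where it was well above background on both arrays of at least 1 group, and the probe with the highest mean stood for a feature with several. This left 22953 features with the attached files and 23153 with the value table.

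Models were fitted to all 8 arrays with group as the only term, using lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values in the text are limma's. The 2 comparisons were peptide against non-treatment and overexpressor against wild type, and a further contrast tested the difference between the 2 effects. Errors are standard errors of the log2 fold change unless SD is written, with n = 2 arrays per group. The small number of arrays limits the precision. Where a probe was not well above background on either array of the dimmer group, only a bound is given, except in the test of the difference and in the values under other settings. No fold change is given where fewer than 2 of the 4 arrays were well above background. The bound sets the mean of the brighter group against a mean over the dimmer arrays. Each dimmer array enters with the higher of its lowest value well above background and the probe's own value. The bound has no standard error, so error in the group means is not allowed for.

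Slide and comparison coincide: slide 1 holds peptide and non-treatment, slide 2 overexpressor and wild type, so each comparison lies within a slide. By the value table's headings, controls sat at positions 1 and 3 of both slides and treated or overexpressing samples at positions 2 and 4. Position and group cannot be told apart under that labelling.

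There were 22 gene lists, fixed before the data were examined. They cover PROPEP genes and PEPR receptors, pattern-triggered immunity, jasmonate, salicylic acid, ethylene, camalexin and indole glucosinolates, aliphatic glucosinolates, abscisic acid with drought and cold, salt ion transport, oxidative stress, flavonoids, photosynthesis, cell cycle, auxin, iron deficiency, phosphate starvation, heat shock, circadian clock and touch, and markers of root, seed storage and flower. Of 384 members, 5 were dropped because no source used here lists the symbol at that locus, and 341 were tested. Seed storage markers had fewer than 3 tested members (0), so 21 lists were tested in each comparison. limma's camera with a preset correlation of 0.01 compared each list with all other features, adjusted over 42 tests. With an estimated correlation 0 of the 42 tests of the value table passed, and the lowest adjusted p was 0.15. The estimates ranged up to 0.69, for aliphatic glucosinolates. They were -0.011 for pattern-triggered immunity and -0.0015 for salicylic acid, below the preset value. A higher correlation between genes is therefore not what ended the peptide calls of those lists. For the other lists too, the loss of a call is by itself no evidence of correlation between genes.

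Genes are named by a rule fixed before the data were examined. It takes the PROPEP genes and PEPR receptors. Per comparison it takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with both arrays of a group above both of the other and well above background in the brighter group. It takes up to 4 passing members per list, or up to 2 given as values, then 3 sORFs in each direction, and the 10 genes with the smallest p of the difference.

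Scripts were tested on simulated data drawn from the value table's means and SDs for 23153 features, with 100 genes changed at each of 2 sizes per comparison. For peptide against non-treatment, 87 of 100 genes changed by 1 log2 unit and 95 of 100 changed by 2 were recovered, with 8 false calls. For overexpressor against wild type these were 76 and 89 of 100, with 11 false calls. Alternatives tried were normexp background correction with an offset of 50, quantile and median scaling, other filters, the mean of all probes, a mean-variance trend, a replicate block, each array left out, separate fits of the 4 arrays of a comparison, a 2-fold minimum, an estimated correlation and fry. Figures were drawn with matplotlib 3.10.9.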

Results

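The data were 8 one-colour arrays of Arabidopsis seedling RNA on 2 slides, with 2 biological replicates in each of 4 groups. One slide set seedlings given the AT13 peptide against non-treated seedlings, and the other set plants overexpressing AT13 against wild type. AT13 is PROPEP3, which encodes the precursor of the elicitor peptide Pep3, a signal perceived by the receptors PEPR1 and PEPR2. The comparisons ask which transcripts differ when the peptide is supplied from outside and when its precursor gene is overexpressed. The 75th percentile of the processed signal ranged from 643.4 to 816.7 intensity units across arrays.

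PROPEP3 was the label check, because its transcript is the one overexpressed. The gene (AT5G64905) lies on chromosome 5 from 25939574 to 25940059 in the coordinates of the array's design, and exon positions were not analysed here. It was read by the probe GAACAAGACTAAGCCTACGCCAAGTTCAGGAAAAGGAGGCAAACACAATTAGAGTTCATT. In the value table the signal was 151000 and 146000 in the overexpressor columns and 63.3 and 55.2 in the wild type columns. In the scanner files as attached it was 141000 in wild type 2 and 154000 in overexpressor 2, against 70.2 in wild type 1 and 58.9 in overexpressor 1. The scanner files attached to wild type 2 and overexpressor 1 thus go against their labels in this gene. PROPEP3 was not overexpressed on the slide of the peptide treatment, where it lay between 88.7 and 131 in the scanner files, so it does not check the labels there.

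**Figure D1:**
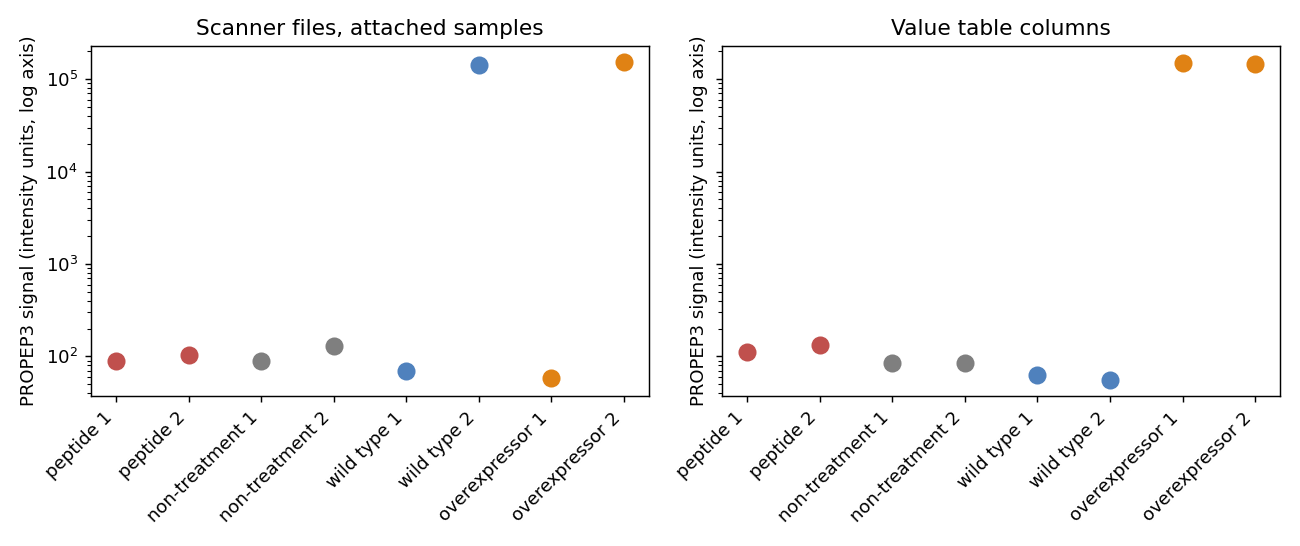
PROPEP3 signal (intensity units, log axis) on each of the 8 arrays, 1 point per array, by the sample each scanner file is attached to (left) and by the value table's column headings (right). On the left 1 wild type file (141000) and 1 overexpressor file (154000) are high, and on the right both overexpressor columns (151000 and 146000) are.

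With the scanner files under the samples they are attached to, which was the main fit, limma called 0 of 22953 features for peptide against non-treatment. It called 0 for overexpressor against wild type and 0 for the difference between the 2 effects. At an unadjusted p under 0.05 there were 222, 317 and 314 features. In that fit the camera test called 2 lists, both for the peptide. Auxin response genes were higher (18 tested, median log2 fold change 0.28, adjusted p = 0.00021) and aliphatic glucosinolate genes lower (12 tested, median -0.24, adjusted p = 0.00072), each with an adjusted p of 1 with an estimated correlation. What follows describes the value table, in which the same fit called 1809, 6927 and 2690 of 23153 features. The named genes that passed in the value table did not pass with the attached files. Of 68 such genes for the peptide, 57 were tested there, 0 passed and 34 had the same sign. Of 96 for the overexpressor, 83 were tested there, 0 passed and 33 had the same sign. Each attached group holds 1 array of each group that the value table's headings name on its slide. If those headings are right, a treatment or genotype effect cancels within the attached groups. The 0 calls, the signs and the 2 lists of the attached fit are then no test of the directions below. Every direction, count and p-value below therefore rests on the value table's column headings. The p-values do not allow for the choice between the 2 labellings, which was made after both results had been seen.

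In peptide-treated seedlings, by the value table, some genes of pattern-triggered immunity, jasmonate, camalexin and phosphate starvation rose, and some anthocyanin, cell cycle and abscisic acid genes fell. These lists passed as sets with the preset correlation, and 0 passed with an estimated correlation (adjusted p of 0.15 to 0.43). PEPC1 (AT1G17710), annotated as a phosphatase, rose by 3.51 ± 0.23 log2 units, 11.4-fold (adjusted p = 0.0026). The chitinase gene AT2G43620 rose 7.68-fold (log2 2.94 ± 0.12, adjusted p = 0.00065), from a signal of 4990 and 5850 to 43600 and 39500. The receptor-like protein gene RLP21 rose 6.80-fold (2.77 ± 0.10, adjusted p = 0.00059). SP1L5, a relative of the microtubule protein SPIRAL1, fell by 2.80 ± 0.066 (adjusted p = 9.2e-05), and LEA7, a late embryogenesis abundant gene, fell by 2.57 ± 0.16 (adjusted p = 0.0025).

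The other large rises were of AT1G14250, a nucleoside phosphatase gene (3.03 ± 0.11), the cytochrome P450 gene CYP710A4 (2.72 ± 0.47) and the thioredoxin family gene AT1G03020 (2.60 ± 0.23). For 4 genes that were not well above background without treatment a bound applies. The flowering signal gene FT was at least 3.56-fold higher, the thionin gene AT1G66100 at least 6.29-fold, AT5G52390 at least 6.47-fold and the beta-glucosidase gene BGLU28 at least 3.75-fold. AT5G36130, of the cytochrome P450 family, fell by 2.86 ± 0.12. The remaining falls were to signals not well above background. The lipase family gene AT5G33370 was at least 6.76-fold lower, the oxidoreductase gene AT1G12570 at least 2.68-fold, AT1G70270 at least 1.96-fold, the GH3 family gene AT1G48660 at least 1.42-fold and the sugar transporter gene SWEET4 at least 1.24-fold.

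Among PROPEP genes and PEPR receptors, 2 of 9 rose with the peptide and 0 fell (3 and 0 adjusted over the list alone). PROPEP3 itself rose by 0.53 ± 0.11 (adjusted p = 0.038) and PROPEP2 by 0.64 ± 0.13 (adjusted p = 0.037). PROPEP1 (0.40 ± 0.12, adjusted p = 0.11) and PEPR1 (0.16 ± 0.084, adjusted p = 0.30) did not pass. The log2 fold changes of PROPEP4, PROPEP5, PROPEP6, PROPEP7 and PEPR2, none of which passed, were -0.18, 0.090, -0.061, 0.19 and 0.090. The list did not pass as a set (adjusted p = 0.069).

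Pattern-triggered immunity genes were higher as a set (camera adjusted p = 1.2e-06), with 8 of 29 rising, 1 falling and 20 not passing (14 and 1 adjusted over the list alone). The receptor kinase gene FRK1, a common marker of this response, rose by 1.74 ± 0.18, and the transcription factor gene WRKY53 by 1.02 ± 0.14. WRKY30 was at least 1.94-fold higher, and NHL10 fell by 1.01 ± 0.18. With an estimated correlation the set had an adjusted p of 0.15. In the jasmonate list 7 of 33 rose and 0 fell (13 and 0 adjusted over the list alone), with a camera adjusted p of 0.00018 and an adjusted p of 0.43 with an estimated correlation, and 0.067 with fry. Its passing members included ERF1 (1.42 ± 0.23), the allene oxide cyclase gene AOC1 (1.06 ± 0.15) and the repressor genes JAZ9 (0.92 ± 0.095) and JAZ5 (0.86 ± 0.14). In the camalexin and indole glucosinolate list 6 of 18 rose and 1 fell (9 and 1 adjusted over the list alone). Its camera adjusted p was 0.00081, and its adjusted p was 0.42 with an estimated correlation. PAD3, which makes camalexin, rose by 1.09 ± 0.099, GSTF6 by 1.09 ± 0.12 and GGP1 by 0.70 ± 0.068, while MYB34, a regulator of indole glucosinolates, fell by 0.63 ± 0.063.

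Salicylic acid genes were higher as a set (adjusted p = 0.012, and adjusted p = 0.32 with an estimated correlation), with 3 of 15 rising and 1 falling (7 and 1 adjusted over the list alone). FMO1 rose by 0.998 ± 0.13, GRX480 by 0.90 ± 0.19 and PR5 by 0.66 ± 0.079, and the gene counted as falling, ALD1, was well above background on 1 of the 4 arrays, so no fold change is given. The set did not pass without non-treatment 1 (adjusted p = 0.07) or, on re-assigned scanner values, with median normalization (adjusted p = 0.07). Phosphate starvation genes were higher, with 4 of 10 rising and 0 falling (4 and 1 adjusted over the list alone). The set had an adjusted p of 0.00026, and an adjusted p of 0.32 with an estimated correlation. The acid phosphatase gene PAP17 rose by 1.83 ± 0.17, the phosphate sensor gene SPX1 by 1.32 ± 0.10 and the transporter gene PHT1;4 by 0.72 ± 0.086, and SPX3 was at least 2.34-fold higher. Of 3 touch genes TCH2 rose, by 0.69 ± 0.098 (set adjusted p = 0.035, and adjusted p = 0.40 with an estimated correlation; 2 rose adjusted over the list alone). The touch list did not pass without peptide 1 (adjusted p = 0.08) or without non-treatment 2 (adjusted p = 0.074).

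Flavonoid and anthocyanin genes were lower, with 5 of 14 falling and 1 rising (9 and 1 adjusted over the list alone). The set had an adjusted p of 0.00014, and an adjusted p of 0.32 with an estimated correlation. LDOX, the anthocyanidin synthase gene, fell by 1.55 ± 0.13, GSTF12 fell by 1.84 ± 0.28 and F3H fell by 0.90 ± 0.10, and DFR was at least 2.18-fold lower. Cell cycle genes were lower (set adjusted p = 1.2e-06, and adjusted p = 0.32 with an estimated correlation), with 6 of 20 falling and 0 rising (14 and 0 adjusted over the list alone). CDC20.1 fell by 0.59 ± 0.097, the cyclin genes CYCB1;1 by 0.55 ± 0.11 and CYCB2;1 by 0.49 ± 0.092, and KNOLLE by 0.40 ± 0.091. In the abscisic acid, drought and cold list 8 of 36 fell and 2 rose (15 and 3 adjusted over the list alone). The set had an adjusted p of 0.0082, and an adjusted p of 0.42 with an estimated correlation. Besides LEA7, RAB18 fell by 0.97 ± 0.16 and HAI3 was at least 1.36-fold lower, while NAC019 was at least 3.42-fold higher. The set did not pass without non-treatment 1 (adjusted p = 0.17) or with fry (adjusted p = 0.063). Auxin response genes were lower as a set (adjusted p = 0.0016, and adjusted p = 0.42 with an estimated correlation), with 1 of 17 falling, GH3.2 by 0.56 ± 0.085 (1 adjusted over the list alone). The set did not pass without non-treatment 1 or with fry (adjusted p = 0.067). With the attached files its direction was the opposite, which is no test of it if the table's headings are right.

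The remaining lists did not pass as sets. In the ethylene list 1 rose and 1 fell of 15 (3 and 2 adjusted over the list alone, set adjusted p = 0.072), with ACO1 falling by 0.68 ± 0.081. In the oxidative stress list 1 rose and 3 fell of 21 (3 and 5 adjusted over the list alone, set adjusted p = 0.94). GSTU24 fell by 1.35 ± 0.12 and GSTU25 by 1.05 ± 0.093, OXI1 was at least 1.67-fold lower, and PRX71 rose by 0.69 ± 0.11. Its median was 0.069 and its mean -0.099. LHCB3 was the 1 photosynthesis gene of 35 to fall, by 0.56 ± 0.086 (1 adjusted over the list alone, set adjusted p = 0.18), and 1 of 16 root markers fell, PLT1 by 1.26 ± 0.14 (3 adjusted over the list alone, set adjusted p = 0.068). Of 6 flower markers FT and PI rose, the latter by 0.96 ± 0.21 (2 and 1 adjusted over the list alone, set adjusted p = 0.66), with a median of -0.060 and a mean of 0.50. In 5 lists 0 members passed, also adjusted over the list alone. These were aliphatic glucosinolates (12 tested, set adjusted p = 0.086), salt ion transport (6, 0.27), iron deficiency (5, 0.052), heat shock (7, 0.49) and the circadian clock (14, 0.50). Their members with the largest values were MYB29 at 0.47 ± 0.16, SOS3 at 0.40 ± 0.18, BHLH39 (at least 1.24-fold lower by its signal, not passing), HSP23.6 at -0.75 ± 0.43 and PRR9, which was well above background on 1 of the 4 arrays. The iron deficiency set passed as lower with the length trend removed (adjusted p = 0.039) and with fry (adjusted p = 0.013). The clock list had a median of -0.022 and a mean of 0.036.

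In all, 1809 of 23153 features (7.81%) passed for the peptide in the value table, 985 higher and 824 lower, and 369 of them differed at least 2-fold. Among 1021 sORFs, 20 were higher and 19 lower. The sORF on chromosome 5 from 14889303 to 14889482 rose by 1.52 ± 0.12, that on chromosome 1 from 2407651 to 2407785 by 1.32 ± 0.14 and that on chromosome 2 from 19220327 to 19220434 by 1.304 ± 0.17. The sORF on chromosome 1 from 1636295 to 1636399 fell by 1.25 ± 0.097 (adjusted p = 0.0031), and those on chromosome 1 from 3548018 to 3548134 and on chromosome 4 from 1158812 to 1159084 were at least 1.09-fold and 1.28-fold lower. The count was 356 without peptide 1, 501 without peptide 2, 910 without non-treatment 1 and 712 without non-treatment 2. Scanner values under the table's headings gave 952 higher and 1090 lower with the 75th percentile, 1815 and 721 after median scaling, and 486 and 248 after normexp with the few bright local backgrounds replaced.

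In overexpressing plants, by the value table, PROPEP3 was 2510-fold higher than in wild type (log2 11.29 ± 0.11, adjusted p = 3.1e-07). Of the phosphate starvation list 7 of 10 genes rose, and 14 of 36 abscisic acid, 9 of 12 aliphatic glucosinolate and 4 of 7 heat shock genes fell. These lists passed as sets with the preset correlation, and 0 passed with an estimated correlation (adjusted p of 0.32 to 0.43). CRK37 (AT4G04500), a cysteine-rich receptor-like kinase gene, was at least 427-fold higher, and its neighbour CRK38 at least 2.57-fold. AT5G24240, annotated as a phosphatidylinositol kinase, rose by 6.10 ± 0.17 (adjusted p = 0.00014), and the overlapping locus AT5G24250 was at least 2.90-fold higher. AT5G05250, of unknown function, fell by 4.15 ± 0.31 (adjusted p = 0.0032), 17.8-fold.

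AT3G25240 rose by 2.63 ± 0.30, AT1G03020 by 2.49 ± 0.23 and AT5G20790 by 2.47 ± 0.27. The homeodomain gene HDG8 was at least 1.74-fold higher and AT3G33528 at least 4.30-fold. AT2G30766 fell by 3.70 ± 0.37, AT1G74250, of the DNAJ family, by 3.06 ± 0.18 and AT3G24080, of the KRR1 family, by 2.96 ± 0.28. The other large falls were to signals not well above background: FDM4 was at least 6.02-fold lower, AT1G75260 at least 2.60-fold, AT5G42880 at least 2.39-fold, the histone acetyltransferase gene HAC4 at least 2.03-fold, AT5G53230 at least 1.87-fold and AT3G23450 at least 1.80-fold.

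Of the PROPEP and PEPR genes, 4 of 9 rose and 0 fell (4 and 0 adjusted over the list alone, set adjusted p = 0.068). Besides PROPEP3 these were PROPEP7 (0.81 ± 0.17), PROPEP4 (0.52 ± 0.13) and PROPEP6 (0.52 ± 0.097). PROPEP4 did not pass once the trend with gene length was removed (adjusted p = 0.076). The values of PROPEP1, PROPEP2, PROPEP5, PEPR1 and PEPR2, none of which passed, were 0.052, -0.18, 0.17, 0.039 and -0.23.

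Phosphate starvation genes were higher, with 7 of 10 rising and 0 falling (7 and 0 adjusted over the list alone). The set had an adjusted p of 0.00018, and an adjusted p of 0.32 with an estimated correlation. AT4, a non-coding RNA gene of phosphate starvation, rose by 2.07 ± 0.28, SPX1 by 1.71 ± 0.10 and MGD2, for galactolipid synthesis, by 1.41 ± 0.33, and SPX3 was at least 2.47-fold higher. In the abscisic acid, drought and cold list 14 of 36 fell and 1 rose (21 and 1 adjusted over the list alone). The set had an adjusted p of 0.00014, and an adjusted p of 0.32 with an estimated correlation. LEA7 fell by 1.32 ± 0.16 and RD29A fell by 1.09 ± 0.21, and the phosphatase gene HAI2 was at least 1.46-fold lower. HAI3 is among the 14 but was not well above background on any of these 4 arrays, so no fold change is given. Aliphatic glucosinolate genes were lower, with 9 of 12 falling and 0 rising (10 and 0 adjusted over the list alone). The set had an adjusted p of 0.00037, and an adjusted p of 0.43 with an estimated correlation. The chain-elongation genes MAM3 and MAM1 fell by 0.82 ± 0.13 and 0.68 ± 0.15, the regulator gene MYB29 by 0.74 ± 0.16 and FMOGS-OX1 by 0.63 ± 0.15. Heat shock genes were lower (set adjusted p = 0.0032, and adjusted p = 0.32 with an estimated correlation), with 4 of 7 falling and 0 rising (4 and 0 adjusted over the list alone). HSP70 fell by 0.86 ± 0.14, HSP90.1 by 0.86 ± 0.088, HSP18.2 by 0.84 ± 0.13 and HSP101 by 0.53 ± 0.10.

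The other lists did not pass as sets in the overexpressor. In the immunity list 4 rose and 4 fell of 29 (5 and 7 adjusted over the list alone, set adjusted p = 0.61), with WRKY18 rising by 0.64 ± 0.093 and WRKY46 by 0.58 ± 0.15, and NHL10 falling by 0.81 ± 0.18 and PMR4 by 0.57 ± 0.096. With the length trend removed WRKY46 (adjusted p = 0.065) and PMR4 (adjusted p = 0.081) did not pass. In the jasmonate list 2 rose and 4 fell of 33 (1 and 2 adjusted over the list alone, set adjusted p = 0.94). CORI3 fell by 1.24 ± 0.19 and LOX2 fell by 0.95 ± 0.22, while JAZ9 rose by 0.58 ± 0.095 and AOC1 by 0.52 ± 0.15, the latter not passing with the length trend removed (adjusted p = 0.098). Its median was 0.14 and its mean 0.042, while the set test pointed down. In the salicylic acid list 3 of 15 rose, WRKY70, CBP60G and WRKY54, the first by 0.83 ± 0.15 and the last not passing with the length trend removed (adjusted p = 0.074; 3 adjusted over the list alone, set adjusted p = 0.073). The set passed as higher with the length trend removed (adjusted p = 0.03) and with fry (adjusted p = 0.014). In the ethylene list 3 rose and 1 fell of 15 (3 and 1 adjusted over the list alone, set adjusted p = 0.77), ERF4 by 0.44 ± 0.093. In the camalexin and indole glucosinolate list 3 rose and 5 fell of 18 (3 and 5 adjusted over the list alone, set adjusted p = 0.38). UGT74B1 fell by 0.83 ± 0.14 and CYP79B2 by 0.74 ± 0.15, while PAD3 rose by 0.47 ± 0.099.

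Of 35 photosynthesis genes 7 rose and 1 fell (3 and 1 adjusted over the list alone, set adjusted p = 0.13), among them PSBR, up by 0.47 ± 0.075, and LHCB3, up by 0.37 ± 0.086 and not passing with the length trend removed (adjusted p = 0.086). In the oxidative stress list 1 rose and 4 fell of 21 (1 and 4 adjusted over the list alone, set adjusted p = 0.052), including RBOHF, which fell by 0.76 ± 0.089, PRX71, which fell by 0.79 ± 0.11, and PER4, which was not well above background on any of the 4 arrays. The oxidative stress set passed as lower with the length trend removed (adjusted p = 0.03) and with fry (adjusted p = 0.0094). In the cell cycle list 2 rose and 3 fell of 20 (2 and 3 adjusted over the list alone, set adjusted p = 0.94), with MCM5 falling by 0.76 ± 0.12, a median of 0.021 and a mean of -0.023. In the auxin list 1 rose and 1 fell of 17 (0 and 1 adjusted over the list alone, set adjusted p = 0.49), LBD16 and GH3.3, the latter with a value of -1.15 ± 0.16. With the length trend removed LBD16 did not pass (adjusted p = 0.089). In the iron deficiency list 1 rose and 2 fell of 5 (2 and 2 adjusted over the list alone, set adjusted p = 0.78), NAS4 with a value of -0.99 ± 0.28, and BHLH39, which was well above background on 1 of the 4 arrays. All 3 touch genes rose, TCH3 by 0.65 ± 0.13 (3 adjusted over the list alone, set adjusted p = 0.068), and TCH4 did not pass with the length trend removed (adjusted p = 0.086). In the clock list 2 rose and 1 fell of 14 (1 and 1 adjusted over the list alone, set adjusted p = 0.66), ELF3 by 0.48 ± 0.081. Of 16 root markers 1 rose and 3 fell (1 and 3 adjusted over the list alone, set adjusted p = 0.49), SCR by 0.75 ± 0.17, and of 6 flower markers 2 rose and 2 fell (2 and 3 adjusted over the list alone, set adjusted p = 0.89), PI rising by 0.91 ± 0.21, with a median of -0.077 and a mean of 0.053. TT8 was the 1 flavonoid gene of 14 to pass, and was not well above background on any of the 4 arrays (1 adjusted over the list alone, set adjusted p = 0.94, median 0.098, mean -0.11). Of 6 salt transport genes 0 passed (0 adjusted over the list alone, set adjusted p = 0.57), with SOS3 at 0.54 ± 0.18.

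**Figure D2:**
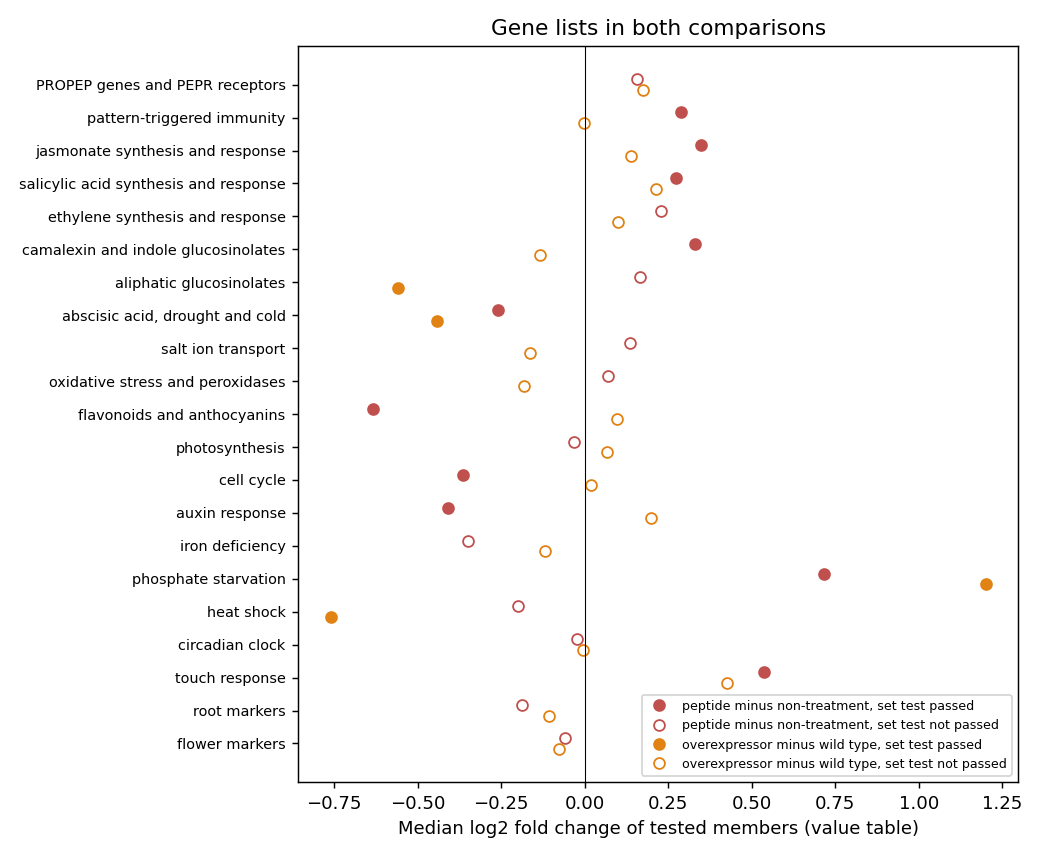
Median log2 fold change (value table) of the tested members of each gene list, 1 point per list and comparison, filled where the camera test with a preset correlation passed. Phosphate starvation genes lie highest in both comparisons, at 0.72 for the peptide and 1.2 for the overexpressor.

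Altogether 6927 of 23153 features (29.9%) passed for the overexpressor in the value table, 3459 higher and 3468 lower, and 666 of them differed at least 2-fold, 126 higher and 540 lower. Fold changes declined with gene length (Pearson r across genes -0.31, and -0.063 for the peptide). With that trend removed 5135 features passed in all. Of the 6135 features with a known length that passed before, 4112 still passed in the same direction. Of 1021 sORFs, 216 were higher and 35 lower, 24.6% in all against 30.2% of genes. The median over all tested sORFs was 0.32, against 0.034 over genes, at a median signal of 24.5 against 472. The fold changes of sORFs as a whole were thus shifted upward at dim signal, and sORFs were not in the fit with the length trend removed. The sORF on chromosome 4 from 10492220 to 10492402 rose by 1.72 ± 0.13, that on chromosome 1 from 2407651 to 2407785, which also rose with the peptide, by 1.57 ± 0.14, and that on chromosome 4 from 4018551 to 4018643 by 1.48 ± 0.42. The sORF on chromosome 5 from 4277695 to 4277790 fell by 1.50 ± 0.19, and those on chromosome 2 from 7851579 to 7851683 and from 3500844 to 3501062 were at least 2.19-fold and 1.44-fold lower. The count was 2948 without wild type 1, 1553 without wild type 2, 2541 without overexpressor 1 and 2658 without overexpressor 2. Scanner values under the table's headings gave 4818 higher and 3365 lower with the 75th percentile, and 6449 and 2813 after median scaling. Between these scalings the median of all features moved from 0.091 to 0.15. In the value table it was 0.049.

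**Figure D3:**
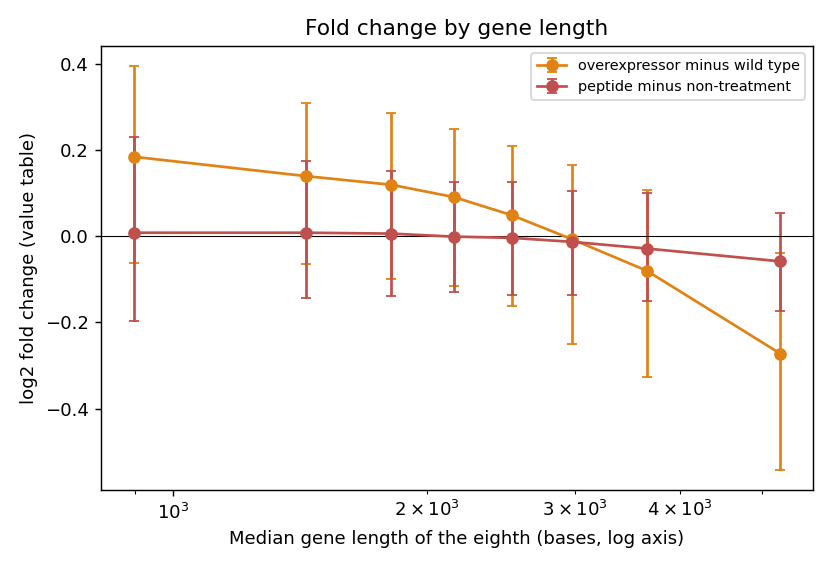
Log2 fold change in the value table against gene length (bases, log axis), as the median of each eighth of the genes by length, with bars from the lower to the upper quartile. The overexpressor's median runs from 0.18 in the shortest eighth to -0.27 in the longest, and the peptide's from 0.0079 to -0.058.

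Across genes the 2 effects in the value table had a Pearson r of 0.17 and a Spearman rho of 0.18. Genes are not independent replicates, so no p is given. With the attached files r was -0.09. By its column headings, 714 features passed in both comparisons, 508 (71.1%) in the same direction. With 1 array left out the overlap was 149 to 445 and r 0.0682 to 0.249. Both rose in 302 and both fell in 206, where independent lists would give 147 and 123. The 101 that rose with the peptide and fell in the overexpressor, and the 105 that did the opposite, compare with 148 and 123. SPX1, SPX3, AT1G03020, JAZ9 and PAD3 passed as higher in both, and LEA7 and NHL10 as lower in both. The comparisons have separate controls, but both share the alternation of control and treated positions on the slide, which cannot be told apart from a shared effect.

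**Figure D4:**
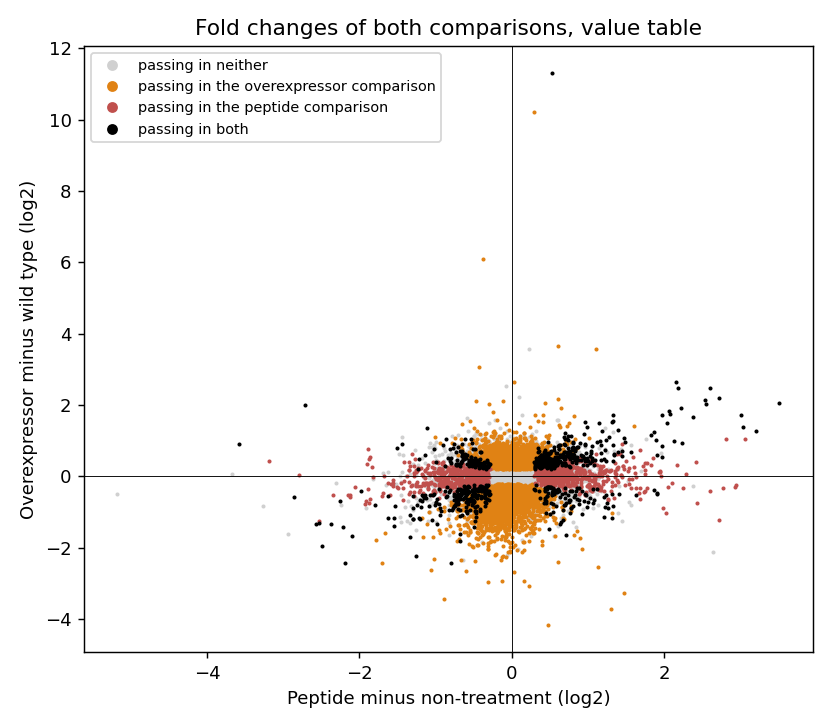
Log2 fold change for peptide minus non-treatment (horizontal) and overexpressor minus wild type (vertical) in the value table, 1 point per tested feature, coloured by the comparisons in which it passed. Of the 714 features that passed in both (black), 508 lie in the quadrants of equal direction.

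The effects differed in 2690 features, 1513 with a higher value for the peptide and 1177 with a lower one. After PROPEP3 (peptide minus overexpressor -10.76 ± 0.15), the smallest p belonged to SP1L5 (-2.85 ± 0.093, adjusted p = 0.00037), which fell with the peptide and had a log2 fold change of 0.054 in the overexpressor. RLP21 (3.08 ± 0.14) and the chitinase gene AT2G43620 (3.18 ± 0.16) rose with the peptide and had values of -0.32 and -0.24 in the overexpressor. AT1G12570, which fell with the peptide, was 0.92 higher in the overexpressor. The count was 468 without peptide 1, 559 without peptide 2, 921 without non-treatment 1, 859 without wild type 1, 475 without wild type 2, 628 without overexpressor 1, 945 without overexpressor 2 and 3113 without non-treatment 2. Scanner values under the table's headings gave 1396 higher and 1845 lower.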

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

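The tests of the labels, of the gene length trend as a whole and of neighbouring genes were chosen after the results had been seen. The tests by signal level and of wild type against non-treatment were set before theirs. By the value table, the peptide effect and the overexpressor effect differed in 2690 features in a test of the difference itself. The 10 genes with the smallest p were PROPEP3 (peptide minus overexpressor -10.8), SP1L5 (-2.85), AT5G24240 (-6.48), AT1G12570 (-4.50), RLP21 (3.08), ATPMEPCRB (1.97), AT2G43620 (3.18), AT2G05510 (1.95), AT1G51913 (2.25) and RTFL15 (-1.45). For AT1G12570 the size rests on a signal not well above background after the peptide. The fall itself is given only as a bound, at least 2.68-fold, without an error. With the attached scanner files the same test called 0 features.

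The first pattern is the disagreement between the value table and the attached scanner files over 6 of 8 arrays. On slide 2, if the files are attached to the right samples, PROPEP3 should be high in both overexpressor files. The lowest overexpressor file lay 11.2 log2 units below the highest wild type file (-11.2), which argues against that attachment. In the value table the lowest overexpressor column lay 11.2 above the highest wild type column, as an exchange of 2 attached files would give. The SD of the log2 difference on slide 2 was 0.21 and 0.207 between value-table columns of a group and 0.414 to 0.447 between groups. On this slide PROPEP3 argues for the table's headings. By this gene the 0 overexpressor calls of the attached files come from mixed groups and are no evidence against an effect. For slide 1 no overexpressed transcript checks the labels. By the value table FRK1 read 136 and 116 in the peptide columns and 32.8 and 43 in the non-treatment columns. On slide 1 the SD of the log2 difference was 0.177 and 0.23 between columns of a group and 0.326 to 0.357 between groups. The arrays thus pair as the value table's headings do, but the pairs are also positions 2 and 4 against 1 and 3, so position could give the same pairing. The files of both slides are attached in order of position, 1 and 2 to 1 group and 3 and 4 to the other. PROPEP3 goes against that order on slide 2, so it is in doubt on slide 1 too, though no transcript settles it there. The number of calls was 0 with the attached files and 1809 with the value table. A labelling cannot be chosen by how many genes it calls, so the 2 labellings of slide 1 are not settled here.

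The second pattern is the decline of the overexpressor's fold changes with gene length. Of 6135 calls with a known length, 4112 (67.0%) were called in the same direction after the trend was removed, which argues against the trend as the whole source of the calls. Within 4 groups of genes by mean signal the weakest correlation with length was -0.281, which argues against signal level. Wild type minus non-treatment correlated with length at 0.363, and overexpressor minus non-treatment at 0.082. A departure of the wild type arrays, in RNA quality or in biology, may therefore carry the trend. The slides were normalized separately, and no test separated RNA quality from genotype.

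The third pattern is the pair CRK37 and CRK38 and the pair AT5G24240 and AT5G24250, among the largest rises in the overexpressor after PROPEP3. In CRK37, AT5G24240 and AT5G24250 the lower overexpressor array lay 9.36, 5.43 and 1.91 log2 units above the highest of the other 6. Each gap was over 2 standard errors of the fold change, which argues against a spot artefact on 1 array for these genes. The naming rule already asked for both overexpressor arrays above both wild type arrays, so only the size of the gaps bears on this. In CRK38 that gap was 1.22, with a standard error of 0.686, so such an artefact stays open for the dim CRK38. AT5G24240 and AT5G24250 overlap by 455 bases, so both probes may read 1 transcript. CRK37 and CRK38 do not overlap (-1256 bases), which argues against overlap for them, while similar sequence was not tested. The highest value among the next tested genes outside the pairs was 0.793, for CRK39. CRK38 ends at 2244930 and CRK39 starts at 2259580, so a nearer gene may not have been tested. Activation beside an inserted transgene cannot be told apart from other sources without reads of the genome.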

How the results depend on the processing

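The replicate-block-within-slide, length-trend, adjusted normexp and re-assigned settings were added after the data were seen, as were all alternatives to the value-table fit. With the attached files, calls for peptide, overexpressor and difference stayed at 0 except as follows. The value table gave 1809, 6927 and 2690 calls, 39 and 251 sORF calls, 10 and 4 gene lists passing and an overlap of 714. Scanner values assigned as in the value table gave 2042, 8183 and 3241, 46 and 300 sORFs, 11 and 5 gene lists and an overlap of 863. With normexp background the overexpressor had 10403 calls (836 higher, 9567 lower), 900 sORF calls and 1 gene list, and the difference 8443. On 2 arrays 6 and 5 spots had local backgrounds over 1000, and with these replaced normexp gave 0 calls. A replicate block within each slide gave 1 overexpressor call. With no filter on dim probes 1 gene list passed in each comparison, and with an estimated correlation or with fry 0 gene lists passed for the peptide. Leaving out 1 array gave 0 to 2 peptide calls, 0 to 1 overexpressor calls, 0 to 2 for the difference, 0 to 0 sORF calls, 2 to 7 and 0 to 4 gene lists, a correlation of the effects of -0.237 to 0.144 and an overlap of 0 to 0. Counting only turns in which either value passed, directions turned for PROPEP2 (0.641) and PROPEP3 (0.527) with the peptide in the value table, and for PROPEP3 in the overexpressor (11.3, and 11.4 with re-assigned scanner values). With normexp they turned for PROPEP1 (-0.476), PROPEP5 (-0.356) and PEPR2 (-1.12).

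For the value table, calls for peptide, overexpressor and difference were 766, 4074 and 498 with no filter on dim probes (60 peptide sORFs, 7 overexpressor gene lists, overlap 207). With a mean-variance trend the peptide had 2824, the difference 4435 and the overlap 1204. A replicate block within each slide gave 914 and 1492 and an overlap of 359. The samples of a pair share only a number (correlation of replicate deviations 0.119 and 0.0579), and a common replicate block gave 1571, 7022 and 2790. Only the 4 arrays of the peptide comparison gave 857. At least 2-fold gave 369, 666 and 811, with 7 and 29 sORFs. Scanner values with normexp background gave 0, 1 and 0 calls, 0 and 0 sORFs, 7 overexpressor gene lists and an overlap of 0. With the bright local backgrounds replaced they gave 734 for the peptide, 1005 for the difference, 9 and 33 sORFs, 7 overexpressor gene lists and an overlap of 226. Median normalization gave 395 overexpressor sORFs and an overlap of 1238. With an estimated correlation 0 and 0 gene lists passed, and with fry 9 for each comparison, where the peptide's jasmonate (adjusted p = 0.067), abscisic acid (0.063) and auxin (0.067) lists did not pass. Passing with fry, and not with camera, were photosynthesis (0.025) and iron deficiency (0.013) for the peptide. For the overexpressor they were PROPEP and PEPR genes (0.0017), salicylic acid (0.014), oxidative stress (0.0094), photosynthesis (0.0084) and touch (0.025). Leaving out 1 array, with a lone sample assumed to vary like the others, gave 356 to 1414, 1553 to 7558 and 468 to 3113 calls, 10 to 42 and 75 to 242 sORFs, 8 to 12 and 4 to 5 gene lists, a correlation of 0.0682 to 0.249 and an overlap of 149 to 445. List calls kept their direction throughout. Without non-treatment 1 the peptide's abscisic acid (adjusted p = 0.17), auxin (0.07) and salicylic acid (0.07) lists did not pass, nor salicylic acid after median normalization (0.07), nor touch without peptide 1 (0.08) or non-treatment 2 (0.074). Of the named values 3299 kept their label, 746 were weaker, 14 stronger and 15 reversed. With normexp on re-assigned scanner values those were ALD1 with the peptide (0.0154, and 0.0154 with adjusted normexp) and, in the overexpressor, HAI3 and PER4 (both 0.0742), TT8 (0.0423), BHLH39 (0.0907), PLT2 (0.0422), PYK10 (0.00491), AG (0.145), AP3 (0.053) and the chromosome 2 sORFs from 7851579 (0.0344) and 3500844 (0.116). PYK10 also turned with the 75th percentile (0.0689), adjusted normexp (0.0536) and median normalization (0.128).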

Other observations

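The 16 gene families here were picked by words in the array's descriptions after the value table's results had been seen, and tested with camera over 32 tests. With an estimated correlation 0 of these tests passed, with adjusted p-values of 0.26 or more. By the value table, cysteine-rich receptor-like kinase genes were higher after the peptide (31 tested, 8 rose, 1 fell, median 0.34, adjusted p = 3.5e-08), as were WRKY genes (54 tested, 12 rose, 1 fell, median 0.11, adjusted p = 0.00099). Ribosomal protein genes were lower after the peptide as a set (342 tested, 0 rose, 11 fell, median -0.15, adjusted p = 2e-10). A smaller share of them passed than the 7.81% of all features. Kinesin and myosin genes (0 rose, 2 fell, median -0.17, adjusted p = 0.0086) were also lower. So were DEAD-box and DEAH-box helicase genes (0 rose, 2 fell, median -0.10, adjusted p = 0.0089). Neither of these 2 families passed with the length trend removed (adjusted p = 0.067 for each).

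In the overexpressor, by the value table, WRKY genes were lower (10 rose, 15 fell, median -0.20, adjusted p = 0.027, and 0.0095 with the length trend removed). Kinesin and myosin genes were lower (61 tested, 2 rose, 35 fell, median -0.44, adjusted p = 3.6e-09), as were DEAD-box and DEAH-box helicase genes (58 tested, 1 rose, 26 fell, median -0.33, adjusted p = 6.3e-06). These are long genes, with median lengths of 4850 and 4098.5 bases. With the length trend removed the medians were -0.20 (adjusted p = 0.0027) and -0.10 (adjusted p = 0.13). SAUR genes, with a median length of 812 bases, were higher (67 tested, 20 rose, 1 fell, median 0.34, adjusted p = 4e-04), with a median of 0.17 and an adjusted p of 0.074 without the trend. Glycine-rich protein genes were lower both ways, with medians of -0.23 (adjusted p = 0.0013) and -0.27 (adjusted p = 2.7e-05).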
